A study of Oryctolagus cuniculus with 3 samples.

How the data were processed

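Total RNA of day 6 rabbit embryos was measured on 3 Agilent rabbit oligonucleotide arrays with 2 channels each. Per the labels' protocols, 100 ng of total RNA was labelled per sample. The same protocols describe the vitrification, which took place at 20 °C. Morulae spent 2 min in 12.5% dimethyl sulphoxide and 12.5% ethylene glycol and then 30 s in 20% of each before straws of 0.25 ml were plunged into liquid nitrogen. Warmed embryos passed through 0.33 M sucrose for 5 min. The slow-freezing protocol is not given in the sources used here. The labels state the dyes of each array. Frozen embryos were in Cy5 and vitrified embryos in Cy3 on replicates 1 and 3, and the dyes were the other way round on replicate 2.

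The authors deposited scanner output for replicates 1 and 3 and a value table of all 3 arrays; scanner output of replicate 2 was not used here. Per the file headers and the submitters' processing notes, the scanner images were read with Agilent Feature Extraction 10.10.1.1. Per the file headers, the scanner files give raw and processed spot intensities in each channel, the processed intensity being background-subtracted, spatially detrended and dye-normalized, and a log10 ratio of red over green. Flags in the files say whether a spot was well above background, saturated or an outlier. The value table as deposited holds log2 ratios, with scale, centring and direction unstated. For replicates 1 and 3 its values equalled the log2 ratio of the processed red over green intensities, with largest differences of 3e-06 and 2e-06. That is frozen over vitrified. The medians of its columns were -0.015, 0.021 and 0.017 for replicates 1, 2 and 3, and the SDs over probes were 0.467, 0.342 and 0.354. The table has 22865 rows, 26 of them control probes. The other 22839 are 52.4% of the 43603 probes of the array, and each was well above background in both channels of both scanner files; the authors' filter is not given in the sources used here. Per channel, 54.4% (green) and 66.0% (red) of spots were well above background on replicate 1, and 58.2% and 68.5% on replicate 3. No probe of the table was saturated there.

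The direction of the column of replicate 2 was settled from the data and is likely, not stated. The 10 spike-in probes in the table, whose ratio follows the dye if each spike-in mix was labelled with its usual dye, correlated at 0.99 between replicates 1 and 3 and at -1.00 between replicate 2 and each of them, so that the column had been turned to frozen over vitrified. A score of probe base composition fitted on replicates 1 and 3, which should also follow the dye, correlated with them at 0.22 and 0.10 and with replicate 2 at -0.10. If the mixes had been added by embryo type instead, the spike-ins would read the other way. Values with the sign of replicate 2 turned were therefore computed too. The table has 0 other columns of sample values.

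Probes were named through accessions (8327 probes), gene identifiers (5299), symbols or synonyms in the current RefSeq table of the rabbit, or transcripts shared with a named probe. Together 14237 probes of the table had a symbol (6510 genes), and 8602 had none. Each gene was represented by its brightest probe by mean log2 signal over the scanner arrays. No genome was used here and no coordinates are given.

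The value table was the source of the main comparison because it alone holds the dye swap. Each log2 ratio was tested against 0 over the 3 arrays with limma 3.58.1 (lmFit, eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05; tables were joined in Python 3.11.15 with pandas 2.3.3. Probes of 1 sign on every array with a mean of at least 1.5-fold were also counted. Gene lists were tested with camera in limma (preset inter-gene correlation 0.01) over the lists with at least 5 measured genes, and again with an estimated correlation and with fry. The test with an estimated correlation takes its degrees of freedom from the arrays, so with 3 of them it has little power. An exact sign-flip test of 3 arrays cannot go below p = 0.25 (2-sided), so none is reported per gene. The labels call the arrays biological replicates, so the spread between them holds embryo and technical variation together. Each array is its own pair of samples, and slide and replicate coincide.

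Before the data were examined, the gene lists, the tests, the processing alternatives and the rule for named genes were fixed. The rule takes genes past the threshold, then up to 10 genes per direction with the largest mean among probes of 1 sign on every array, from each list that passed the 4 members furthest in its direction, from every other list the 2 members with the smallest unadjusted p, and 12 fixed genes. A gene chosen by the second part can have entered by a probe other than its brightest, and its printed values are those of the brightest. Some genes that the rule takes are not reported here.

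The test was tried on simulated arrays of 22839 probes with independent noise of the spread of the real ones and 200 changed probes. It called 2.99% of probes changed by 1.5-fold, 70.1% of those changed by 2-fold and 100% of those changed by 4-fold, and 14 unchanged probes. For camera a separate set of genes was simulated, with the hypoblast list shifted by -0.5 log2 evenly on every array. It called the 1 shifted list and 0 of the others. The noise used limma's moderated SDs, was independent between genes and set no array against the others. The real arrays differ in this, so the shares may overstate what the tests could find in them. PHGDH, 3.78-fold lower, had an adjusted p = 0.55 in limma's test on the real arrays.

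Alternatives were the scanner files of replicates 1 and 3 under 3 kinds of background correction and under filters on dim probes, dye orientation as a covariate, centring, scaling, means over a gene's probes, a trended prior, and leaving out each replicate. Within the table the filters on dim probes move nothing, so they were run on the scanner files. For replicates 1 and 3, normexp was run with an offset of 50 and loess within the array. Turning the sign of replicate 1, and fitting normexp without 13 spots of replicate 1 whose local background was over 10 times the median, were added after seeing the data. So were the minimum span of 500 bases in the comparison of 3' and 5' probes and 3 further lists (serum proteins, erythroid genes and ATF4 targets), in which only genes whose values had not been seen were used.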

Results

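Rabbit morulae recovered on day 3 of development were either slow-frozen or vitrified, transferred to recipient does, and collected 3 days later as late blastocysts. Slow freezing cools embryos gradually, while vitrification turns a concentrated cryoprotectant solution into a glass by plunging it into liquid nitrogen. The comparison asks how the transcriptome of the day 6 embryo differs after the 2 ways of storing the morula. Each of 3 Agilent rabbit arrays held 1 labelled RNA sample from frozen embryos and 1 from vitrified embryos, so that each array is a direct comparison. The labels call the 3 arrays biological replicates, and the dyes were exchanged on replicate 2. Values are log2 ratios of frozen over vitrified, positive where the signal was higher after slow freezing. They cover 22839 probes, of which 14237 carry a gene symbol (6510 genes). Fresh embryos were not analysed here, so every value sets one storage method against the other. The number of arrays limits the precision.

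PHGDH and PSAT1, enzymes of serine synthesis, were among the named genes furthest below 0 and lay below it on all 3 arrays. PHGDH, the enzyme that takes a glycolytic intermediate into the serine pathway, had a mean log2 ratio of -1.92 ± 0.20 (SD, n = 3), a 3.78-fold lower signal in frozen embryos. PSAT1, the next enzyme of that pathway, had -1.68 ± 0.60 (SD, n = 3), and each of its 7 probes lay between -1.90 and -1.68. SLC3A1, a subunit of the cystine transporter, had -1.64 ± 1.41, with -0.02 on replicate 1 against -2.28 and -2.61 on replicates 2 and 3. FGF2, a growth factor, had -1.30 ± 0.73, CHAC1, a glutathione-degrading enzyme, had -1.23 ± 0.42 and KDELR3, a receptor that returns proteins to the endoplasmic reticulum, had -1.08 ± 0.41 (SD, n = 3). These 3 genes were dim, with mean log2 signals of 5.77, 5.74 and 5.91 in this order, against 10.54 for PSAT1. PHGDH and CHAC1 rest on 1 probe each. TFPI, an inhibitor of blood clotting, had -1.19 ± 0.43, ITGA1, a collagen-binding integrin, had -1.10 ± 0.59 and APOB, the protein core of low-density lipoproteins, had -0.99 ± 0.82. QPCT, which forms pyroglutamate at peptide ends, entered by a dimmer probe with a mean of -1.19, while its brightest probe gave -0.44 ± 0.39. The sizes depend on the direction of replicate 2, which is likely but not stated; with its sign turned PHGDH had -0.58, PSAT1 -0.40, SLC3A1 -0.12, FGF2 -0.60, CHAC1 -0.70, KDELR3 -0.67, TFPI -0.24, ITGA1 -0.38, APOB -0.45 and QPCT 0.038.

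At the other end, EMP1, a membrane protein of epithelia, had a mean log2 ratio of 1.55 ± 0.96 (SD, n = 3), a 2.93-fold higher signal in frozen embryos. TRPV5, a calcium channel, had 1.38 ± 0.65, ANGPTL4, an inhibitor of lipoprotein lipase, had 1.32 ± 0.63 and ABCB1, a drug efflux pump, had 1.11 ± 0.40. The 3 probes of TRPV5 lay between 0.21 and 1.39. ASZ1, known from the germ line, had 1.07 ± 0.35 and FBP2, a fructose bisphosphatase, had 1.03 ± 0.22. ARHGAP25 had 0.96 ± 0.44, UPRT had 0.86 ± 0.47 and SLC8A1, a sodium and calcium exchanger, had 0.85 ± 0.41. The brightest probe of SLC26A4, an anion exchanger, gave 0.78 ± 0.85 and was slightly below 0 on replicate 1, at -0.05. With the sign of replicate 2 turned EMP1 had 0.21, TRPV5 0.68, ANGPTL4 0.24, ABCB1 0.34, ASZ1 0.52, FBP2 0.26, ARHGAP25 0.0055, UPRT 0.34, SLC8A1 0.43 and SLC26A4 0.28.

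None of these genes passed the test. With limma's moderated test against 0 and Benjamini-Hochberg adjustment, 0 of 22839 probes had an adjusted p under 0.05, and the smallest adjusted p, that of PHGDH, was 0.55. Without adjustment 1020 probes (4.47%) had p under 0.05, 421 higher and 599 lower in frozen embryos. That share is below the 4.96% of unchanged probes in the simulation, so the count by itself shows no difference. With an intensity trend and a robust prior in the same tool the adjusted and unadjusted counts were 0 and 980. With dye orientation as a covariate they were 0 and 759. Without replicate 1 the test called 796 probes, 243 higher and 553 lower; without replicate 2 or 3 it called 0.

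**Figure D1:**
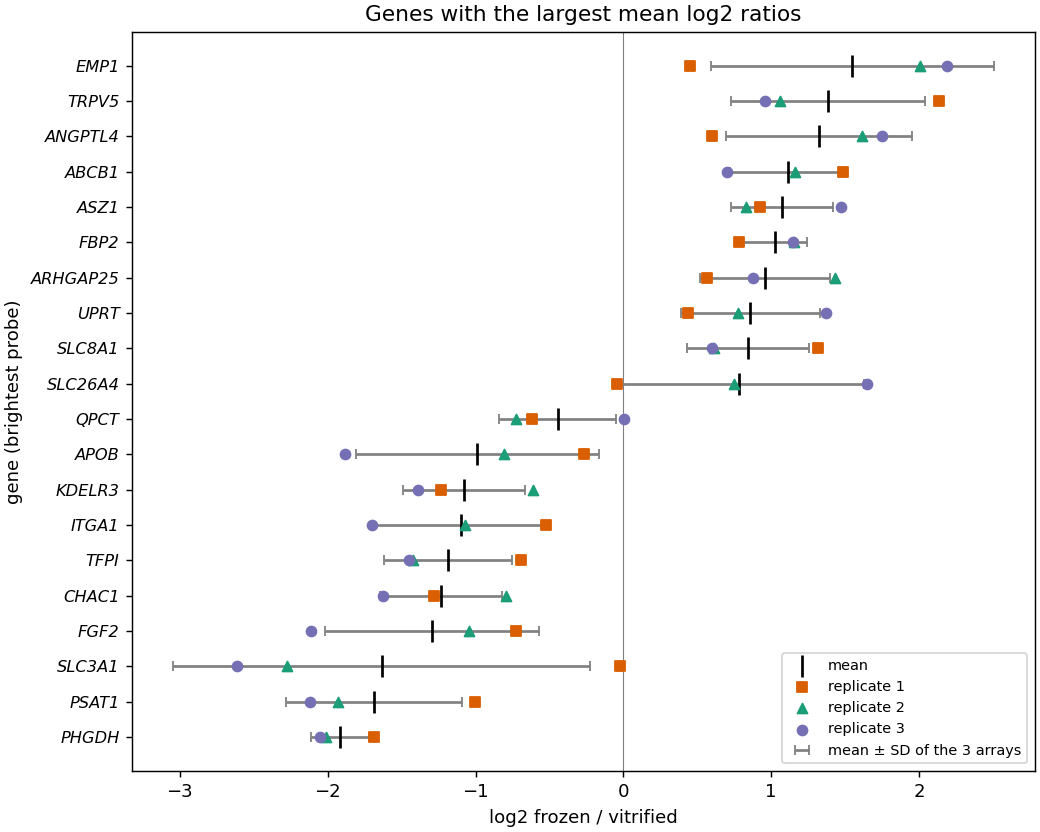
Log2 ratio of frozen over vitrified embryos for the 10 genes per direction that the rule took by any probe of 1 sign on every array, drawn by each gene's brightest probe. Coloured points are the 3 arrays, black ticks the means and grey bars the SD; PHGDH lay between -2.05 and -1.69 on all 3 arrays, while SLC3A1 had -0.02 on replicate 1 and -2.61 on replicate 3.

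Of the gene lists fixed before the data were examined, 26 had at least 5 measured genes, and 3 of them fell in frozen embryos against the other genes in limma's camera at its preset correlation. With an estimated correlation 0 of them passed, each at an adjusted p = 0.85. That test has few degrees of freedom with 3 arrays, so its result does not decide whether correlated genes make the shifts. The estimates were 0.32 for the hypoblast, -0.059 for the unfolded protein response and 0.047 for the matrix list. The hypoblast list, markers of the layer that lines the blastocyst cavity and later gives the yolk sac, had a median log2 ratio of -0.50, with 12 of 14 measured genes below 0 (camera, adjusted p = 2.7e-05; adjusted p = 0.85 with an estimated correlation). APOA1 had -1.03 ± 1.39, RBP4, the carrier of retinol, had -1.02 ± 1.46, APOB had -0.99 ± 0.82 and DKK1, an inhibitor of Wnt signalling, had -0.79 ± 1.19 (SD, n = 3). These were -0.10, 0.29, -0.45 and 0.27 with the sign of replicate 2 turned, and the list's median was then 0.033 (camera, adjusted p = 0.64). The list's median was 0.01 on replicate 1, -0.48 on replicate 2 and -0.65 on replicate 3, and APOA1, RBP4 and DKK1 were above 0 on replicate 1. Below 0 on all 3 arrays were 6 of the 14 genes, among them APOB, COL4A2 and, named after their values were seen, CER1, APOE and GATA4. A red cell gene, HBA1, ran the same way across the arrays, with 1.88 on replicate 1 and -2.23 and -1.79 on replicates 2 and 3. The 3' signal also differed, at 0.24 on replicate 1 against -0.13 and -0.06 on replicates 2 and 3, as replicate 2 is read.

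The list of the unfolded protein response, genes that cells use when proteins misfold in the endoplasmic reticulum, had a median of -0.20, with 12 of 15 genes below 0 (camera, adjusted p = 0.0029; adjusted p = 0.85 with an estimated correlation). It lay below 0 on each array, at -0.15, -0.31 and -0.26 on replicates 1, 2 and 3. CHAC1 had -1.23 ± 0.42, ATF3, a stress-induced transcription factor, had -0.94 ± 0.57, HERPUD1, a factor of protein removal from the endoplasmic reticulum, had -0.56 ± 0.06 and HSPA5, the main chaperone of that compartment, had -0.25 ± 0.21 (SD, n = 3). Adjusted over the list alone, 3 members passed in limma's test, CHAC1 (adjusted p = 0.015), HERPUD1 (0.045) and ATF3 (0.046), against 0 adjusted over all probes. This adjustment was made within each list and not across the 26 lists, where 4 members passed in 2 lists. CHAC1 and ATF3 were dim, with mean log2 signals of 5.74 and 5.67 against 12.89 for HSPA5. CHAC1 and HERPUD1 rest on 1 probe each. With the sign of replicate 2 turned CHAC1 had -0.70, HERPUD1 -0.18, ATF3 -0.71 and HSPA5 -0.23. The list itself no longer passed then, with a median of 0.0081 (camera, adjusted p = 0.98). The sensors ATF6 (0.13 ± 0.09) and EIF2AK3 (0.05 ± 0.10), named after their values were seen, lay above 0.

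The list of extracellular matrix and proteases had a median of -0.17, with 13 of 19 genes below 0 (camera, adjusted p = 0.012; adjusted p = 0.85 with an estimated correlation). FN1, fibronectin, had -0.78 ± 0.33 and each of its 11 probes was below 0. COL4A2 and NID1, which are parts of basement membranes, both had -0.58, with SDs of 0.19 and 0.23, and MMP2, a protease that cuts basement membrane collagen, had -0.58 ± 0.25 (SD, n = 3). FN1 had -0.32, COL4A2 and NID1 -0.24 and MMP2 -0.085 with the sign of replicate 2 turned, and the list's median was then 0.031 (camera, adjusted p = 0.49). This list shares 3 measured genes, COL4A1, COL4A2 and LAMC1, with the hypoblast list. Adjusted over the list alone 0 members passed, as in the hypoblast list. Without replicate 3 the matrix list did not pass (adjusted p = 0.062), and without replicate 2, which is the dye swap, 0 lists passed.

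**Figure D2:**
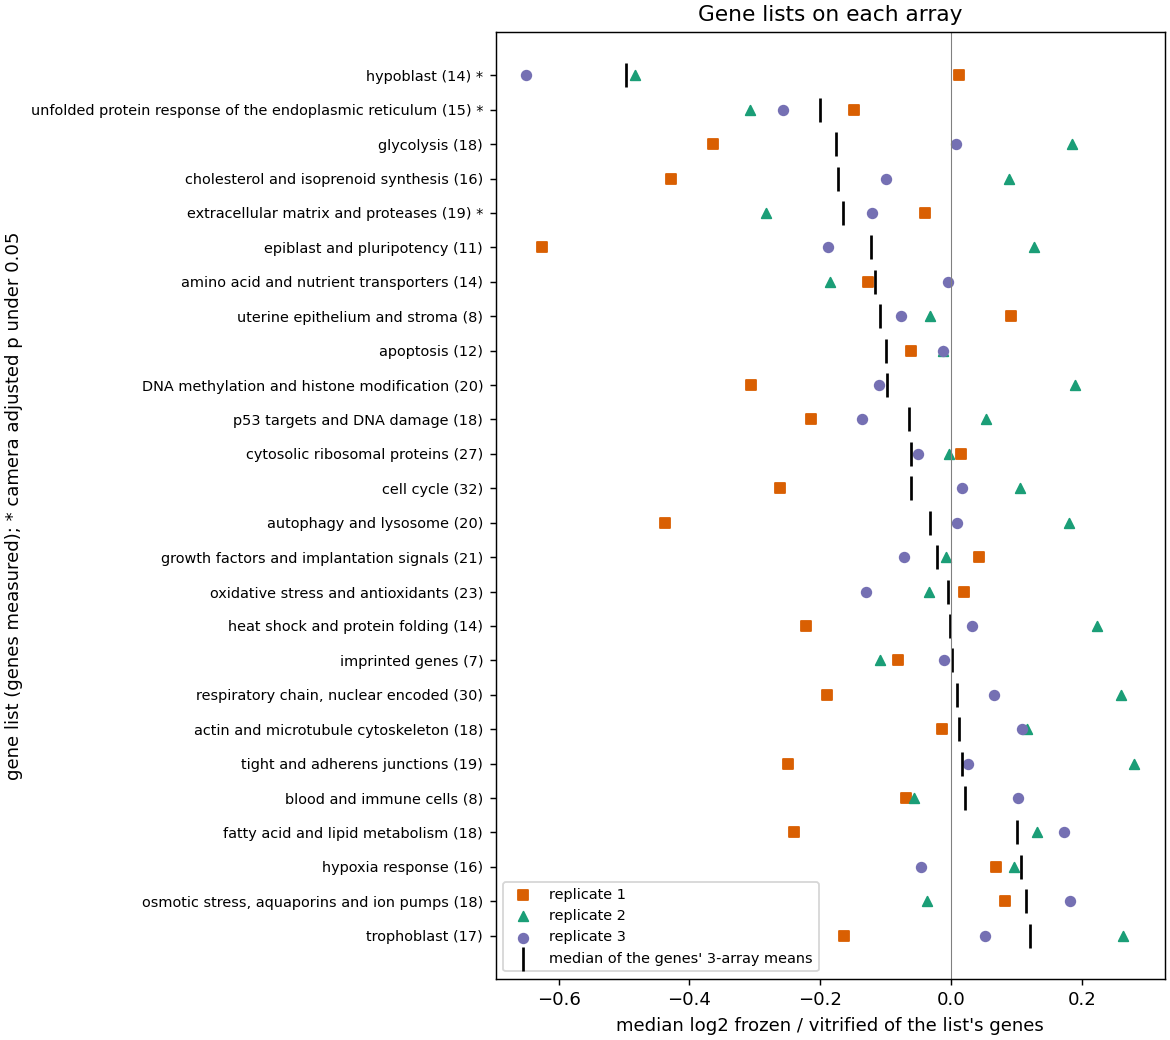
Median log2 ratio of frozen over vitrified embryos over the measured genes of each of the 26 lists, on each array (coloured points) and for the genes' means over the 3 arrays (black ticks). The unfolded protein response list lay below 0 on all 3 arrays, while the hypoblast list was at 0.01 on replicate 1 and at -0.48 and -0.65 on replicates 2 and 3.

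The other lineages of the blastocyst did not pass. The trophoblast list, the outer layer that forms the placenta, had a median of 0.12 with 11 of 17 genes above 0 (camera, adjusted p = 0.19). GATA3, a regulator of that layer, had 0.43 ± 0.42, HAND1 had -0.28 ± 0.10 and the keratin KRT8 had -0.15 ± 0.56 (SD, n = 3). The list's median was -0.16 on replicate 1 and 0.26 and 0.05 on replicates 2 and 3. The epiblast and pluripotency list had a median of -0.12 over 11 genes (camera, adjusted p = 0.35). POU5F1, the pluripotency factor OCT4, had -0.96 ± 0.58, with -0.75, -0.52 and -1.62 on replicates 1, 2 and 3, from 1 probe, and ETV4 had -0.58 ± 0.49. NANOG, SOX2, CDX2 and GATA6 had no named probe and were not analysed here, nor were HSPA8, VEGFA and DNMT1. Of the cells that could come along from the recipient, the list of uterine epithelium and stroma had a median of -0.11 over 8 genes (adjusted p = 0.56). SCGB1A1, uteroglobin, which the rabbit uterus secretes around the blastocyst, had -0.39 ± 0.45, and its 10 probes lay between -1.05 and -0.33. HOXA11 had -0.44 ± 0.51. The list of blood and immune cells had a median of 0.02 over 8 genes (adjusted p = 0.73), with S100A9 at 0.21 ± 0.35. Its red cell gene HBA1 was at -0.71 ± 2.26, with 1.88 on replicate 1 and -2.23 and -1.79 on replicates 2 and 3. The list's mean was -0.06, while its median and the test were on the higher side. With the sign of replicate 2 turned SCGB1A1 had 0.027, HBA1 0.77 and GATA3 0.051. The other genes given a mean in this paragraph kept their sign, as GATA3 did.

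Among stress lists, heat shock and protein folding had a median of 0.00 over 14 genes, with HSPA2 at 0.49 ± 0.55 and CRYAB at -0.26 ± 0.44 (SD, n = 3). The camera test counted that list as higher, although its median and mean were just below 0 (adjusted p = 0.92). The list of oxidative stress and antioxidants had a median of 0.00 over 23 genes (adjusted p = 0.65). Its members split, with 5 above 0 and 5 below 0 on all 3 arrays. TXNIP, an inhibitor of thioredoxin, had 0.53 ± 0.24 and KEAP1 had 0.40 ± 0.13, while SOD1 was at 0.00 ± 0.03. The 2 probes of TXNIP gave 0.069 and 0.53. In this list fry's test for change in either direction gave an adjusted p = 0.0086, and its test for a shift one way gave 0.66. Osmotic stress, aquaporins and ion pumps had a median of 0.11 (adjusted p = 0.25), with ATP1B3 at -0.37 ± 0.09 and SLC9A3 at 0.54 ± 0.55. The p53 list had -0.06 (0.18), with DDB2 at -0.46 ± 0.32 and XPC at -0.33 ± 0.35. The apoptosis list had -0.10 (0.75), with BAX at -0.63 ± 0.56 and AIFM1 at 0.37 ± 0.16. The hypoxia list had 0.11 (0.48). It holds ANGPTL4, which passed adjusted over the list alone (limma, adjusted p = 0.044, with no adjustment across lists), and DDIT4, which had -0.94 ± 0.59. The list of autophagy and lysosome had -0.03 (0.65), with CTSB at -0.35 ± 0.65. With the sign of replicate 2 turned HSPA2 had -0.062, CRYAB 0.25, SLC9A3 -0.0092 and BAX 0.22, each a change of sign. The other genes named in this paragraph kept their sign, with AIFM1 at 0.048.

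The metabolic lists did not pass either, although cholesterol synthesis did in 4 settings on the scanner files of replicates 1 and 3 alone and glycolysis in 2. The nuclear-encoded respiratory chain passed in 3 others, among them without replicate 1. There it did not pass with an estimated correlation, which was 0.63 (camera, adjusted p = 0.81). On replicates 2 and 3 alone that estimate reflects only how unevenly the genes split between higher on replicate 2 and higher on replicate 3. Cholesterol and isoprenoid synthesis had 15 of 16 genes below 0 and a median of -0.17 (camera, adjusted p = 0.099), with ACAT2 at -0.34 ± 0.26 and LSS at -0.42 ± 0.62 (SD, n = 3). Its median was -0.43 on replicate 1, 0.09 on replicate 2 and -0.10 on replicate 3. Glycolysis had -0.18 (0.48), with the lactate carrier SLC16A1 at 0.61 ± 0.27 and LDHB at -0.38 ± 0.10. Fatty acid and lipid metabolism had 0.10 (0.51), with FABP5 at -0.69 ± 0.29 and ACADM at 0.42 ± 0.22. The amino acid and nutrient transporters had -0.12 (0.40), with the glutamine carrier SLC1A5 at -0.70 ± 0.30 and transferrin, TF, at -0.91 ± 0.68. With the sign of replicate 2 turned FABP5 had -0.15, SLC1A5 -0.17 and ACADM -0.027. ACADM was the only gene named in this paragraph to change sign. The nuclear-encoded respiratory chain had 0.01 (0.36), with UQCRB at 0.33 ± 0.10 and SDHD at 0.33 ± 0.13. In it 24 of 30 genes were below 0 on replicate 1 and 3 of 30 on replicate 2; replicate 1 is the array with the 3' signal of 0.24.

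The remaining lists had medians between -0.10 and 0.02. They were cell cycle (camera, adjusted p = 0.53), ribosomal proteins (0.65), DNA methylation and histone modification (0.69), tight and adherens junctions (0.69), cytoskeleton (0.44), growth factors and implantation signals (0.69) and imprinted genes (0.56). The imprinted genes had a median of 0.00 and a mean of -0.10, and the test counted them as lower. SNRPN had -0.52 ± 0.30 and NDN -0.40 ± 0.25 (SD, n = 3). IGF1 had -0.77 ± 0.71, CCND3 -0.44 ± 0.47, CDK4 -0.28 ± 0.41, EZH2 -0.23 ± 0.06, CLDN10 -0.41 ± 0.30 and RPL15 -0.25 ± 0.28. RDX, which ties actin to the membrane, had 0.49 ± 0.08, MSN 0.37 ± 0.11, KAT2B 0.31 ± 0.66, DSG2 0.22 ± 0.22 and RPS12 0.38 ± 0.56. The 3 probes of RDX lay between 0.10 and 0.49. With the sign of replicate 2 turned IGF1 had 0.058 and DSG2 -0.095, while the other genes named in this paragraph kept their sign. The gastrulation and interferon lists had 3 measured genes each and the mitochondrially encoded respiratory chain had 0, so they were not tested on the value table.

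The arrays did not share 1 direction. Across probes, which are not independent replicates, replicates 2 and 3 correlated at Pearson r = 0.48 (Spearman 0.34), replicates 1 and 2 at -0.36 (-0.41) and replicates 1 and 3 at -0.01 (-0.01). On all 3 arrays 22.5% of the probes had 1 sign, where independent signs would give 25%; the share was 26.9% with the sign of replicate 2 turned and 38.5% with that of replicate 1 turned. As labelled, 432 of the probes with 1 sign reached a mean change of at least 1.5-fold, 148 higher and 284 lower in frozen embryos, and they named 32 higher and 106 lower genes. With the sign of replicate 1 turned, 809 probes did so, and with that of replicate 2 turned, 280. The direction of replicate 2 rests on the spike-in probes and base composition. With that sign turned, 0 lists passed and the hypoblast median was 0.03.

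The 3' signal of transcripts differed between arrays as well. In 213 transcripts with probes at least 500 bases apart, the ratio at the 3'-most probe exceeded that at the 5'-most probe by a median of 0.24 on replicate 1 (95% bootstrap interval 0.18 to 0.30). On replicates 2 and 3 the median was -0.13 (-0.17 to -0.10) and -0.06 (-0.10 to -0.02). With the sign of replicate 2 turned its median would lie above 0, as on replicate 1. Each array lay on a slide of its own, so that slide and replicate are 1 factor, and each slide held both kinds of embryo.

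**Figure D3:**
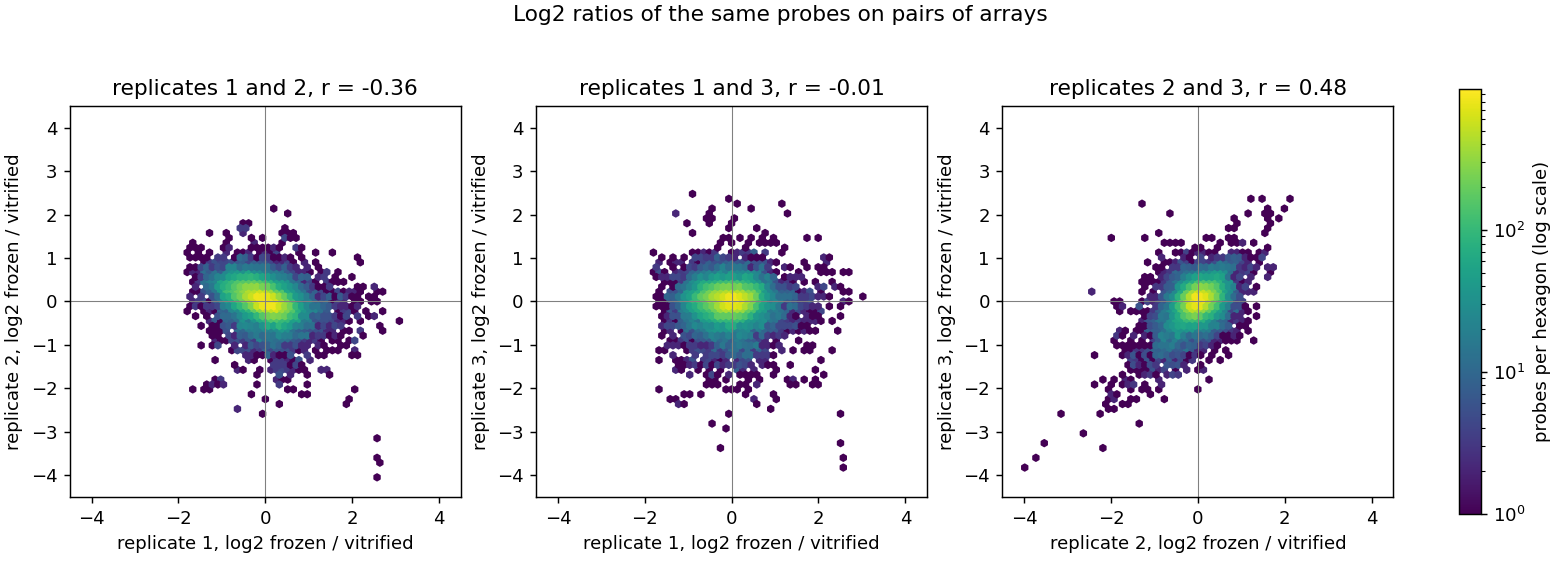
Log2 ratios of frozen over vitrified embryos for 22839 probes on each pair of arrays, with the number of probes per hexagon in colour (log scale). Replicates 2 and 3 lie along a rising diagonal (r = 0.48), replicates 1 and 2 along a falling one (r = -0.36), and replicates 1 and 3 along neither (r = -0.01).

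**Figure D4:**
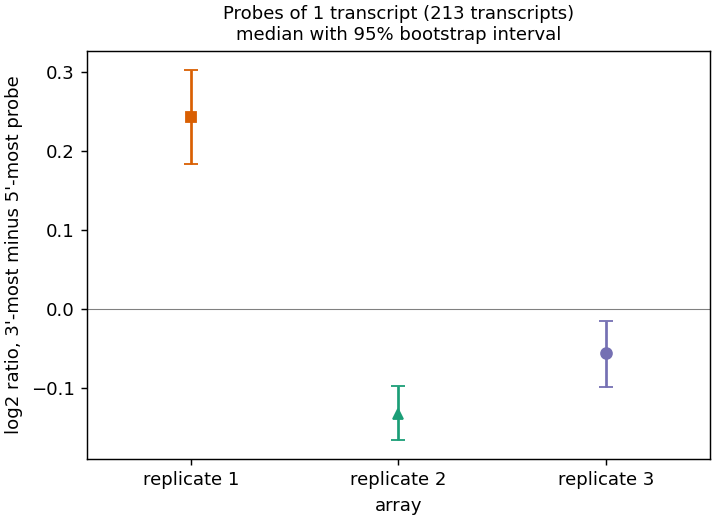
Median over 213 transcripts of the log2 ratio at the 3'-most probe minus that at the 5'-most probe, on each array, with 95% bootstrap intervals over transcripts. Replicate 1 was at 0.24, and replicates 2 and 3 were at -0.13 and -0.06, as the direction of replicate 2 is read.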

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

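The tests of dye effects, and those of the sign patterns for the 2 probe counts, were chosen only after the result was seen. Genes named here outside the fixed rule were chosen after their values were seen. Outside the value table, 254 probes were well above background in both channels of both scanner arrays. These probes were absent from the main comparison and, outlier spots aside, entered only settings on the scanner files of replicates 1 and 3. Among the 254 probes, 142 carry a symbol, and 32 differed by at least 2-fold on replicate 1 and 49 on replicate 3. They have no value on the dye swap, so embryo and dye effects are not separated in them. With 3 arrays no test for a single outlying sample was run.

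With 3 arrays there are 4 sign patterns, too few for a share under 0.05. As labelled, 0 probes passed limma's adjusted threshold, 0 at the highest under another pattern, so that 4 of 4 patterns gave as many. Consistent probes numbered 432 as labelled and 809 at the highest of the others, with replicate 1 turned (2 of 4 patterns gave as many or more). Lists past the threshold numbered 3 as labelled and 3 at the highest of the others (2 of 4). The pattern that follows the dye gave 0, 280 and 0.

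As replicate 2 is read, replicate 1 ran against it (r = -0.36; 0.36 with its sign turned), and of the genes that replicates 2 and 3 alone called, 34.6% of 156 had the same sign on replicate 1 (95% binomial interval 27.2 to 42.6, treating genes as independent), where with that sign turned they called 0 genes. Probe base composition and intensity do not account for it, since r stayed at -0.34 after both were regressed out. An exchange of the embryo labels on replicate 1 stays open, because the interval reaches past the bound of 40% set in advance and the opposition rests on the direction of replicate 2; against it, replicates 1 and 3 correlated at -0.01 and not clearly below 0. A difference in RNA integrity between the embryos of replicate 1 met its prediction, with the 3'-most probe above the 5'-most by a median of 0.24, which is 0.22 after the same regression, and may contribute. Embryo stage or health on the day of collection was not tested.

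Replicates 1 and 3 have the same dyes, yet replicate 1 lay above replicate 3 by a median of 0.39 over the hypoblast list (95% bootstrap interval 0.25 to 1.62). A dye effect alone does not set the values of both arrays. This contrast was chosen after the medians were seen and does not decide whether a dye effect lowers the list on replicates 2 and 3. With the sign of replicate 2 turned the list's median over the 3 arrays was 0.033. A smaller hypoblast or yolk sac share in frozen embryos was tested on 8 serum protein genes not seen before, 0 of them in another list. It stays open, since the higher of their medians on replicates 2 and 3 was -0.094 (95% bootstrap interval -0.13 to 0.15). Of the 38 listed genes 11 were left out because their values had been seen, which may lean the 8 towards genes of little change. Red blood cells carried along were tested on 4 erythroid genes not seen before, 0 of them in another list, with a higher median of 0.087 (0.027 to 0.28). Other cells also express these 4, EPB41, FECH, CA2 and BPGM, so their baseline can hide a small share of red cells and they decide nothing. Carried blood stays open too, since HBB2 was at 2.62 on replicate 1 and at -3.77 and -3.59 on replicates 2 and 3, beside HBA1.

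A dye effect on the serine synthesis and stress genes stays open, because the direction of replicate 2 is only likely: as read, PHGDH, PSAT1, CHAC1 and KDELR3 were all below 0 on it, the highest at -0.61, and with its sign turned they would follow the dye (PHGDH at a mean of -0.58). Lower activity of ATF4, a transcription factor known to drive PHGDH, PSAT1 and CHAC1, is a candidate explanation. Of ATF4 targets not seen before, 19 were measured (1 of them also in another list), and their median of -0.14 lay at percentile 0.14, on a scale from 0 to 100, of 10000 random lists matched on intensity, at 0.32 on replicates 2 and 3 alone, and at 4.02 with the sign of replicate 2 turned. The medians were -0.48, -0.13 and -0.07 on replicates 1, 2 and 3. By mean 14 of the 19 lay below 0, with STC2 at -1.02 and ALDH18A1 at -0.61, while PCK2 was at 0.19 and BCAT1 at 0.18. On both replicates 2 and 3, 10 of the 19 lay below 0. The random lists draw genes independently, while the listed aminoacyl-tRNA synthetase genes all lay below 0 on replicate 1, from WARS1 at -1.01 to EPRS1 at -0.049. If listed genes move together, the percentile is too small. The epiblast and autophagy lists were also low on replicate 1, with medians of -0.63 and -0.44. Lower ATF4 activity stays an open hypothesis, since it also rests on the direction of replicate 2 and comes from the same 3 arrays.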

How the results depend on the processing

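The settings with the sign of replicate 1 turned, and with normexp fitted without spots of very high local background, were chosen only after the result was seen. Each array's ratio is already the pair of a frozen and a vitrified sample, so no further block was fitted. Leaving out 1 replicate at a time gave 0 to 796 probes past the limma threshold (796 without replicate 1), 469 to 1193 consistent probes and 0 to 4 lists (0 without replicate 2). The list medians then ran from -0.57 to -0.34 for the hypoblast, from -0.18 to -0.14 for the unfolded protein response and from -0.20 to -0.17 for the matrix. In every other setting 0 probes passed. With the sign of replicate 2 turned there were 280 consistent probes and 0 lists, the medians of those 3 lists were 0.033, 0.0081 and 0.031, and r was 0.36 for replicates 1 and 2 and -0.48 for replicates 2 and 3. With the sign of replicate 1 turned there were 809 consistent probes, r of replicates 1 and 2 was 0.36 and the unfolded protein response, at -0.15, no longer passed. These signs follow from the turn itself. The scanner values of replicates 1 and 3 alone, which lack the dye swap, gave 2854 consistent probes, medians of -0.41, -0.18 and -0.012 in the same order of lists, none passing, and r = 0.27. With no filter on dim probes they gave 12084, 0 lists, -0.30, -0.059 and 0.030, and r = 0.41; with both channels well above background 1115, 0 lists, -0.38, -0.14 and -0.20. Normexp and loess on them gave 283 consistent probes and 5 lists, with the hypoblast at -0.23 and the matrix at -0.039 not passing. Joined to replicate 2 this gave 155 and 5 lists. Loess without background correction gave 5 lists, with the hypoblast at -0.24 and the matrix at -0.00954 not passing. Normexp fitted without 13 spots of very high local background on replicate 1 gave -0.24, -0.12 and -0.026, none passing; with them its fitted mean red background there was -661, against -4.86. The mean of a gene's probes gave 102 consistent genes, since fewer units are counted. With an estimated correlation, and with fry's test for a shift one way, 0 lists passed, at the same medians of -0.50, -0.20 and -0.17. Centring, scaling and dye as a covariate left the 3 list calls past the threshold. The trended prior entered only the test of probes, so it could not change the list calls. Cholesterol synthesis passed in the scanner settings with processed values, with either normexp fit and with no background correction, and glycolysis in those with the first normexp fit and with no correction. Ribosomal proteins passed in 4 settings, the nuclear-encoded respiratory chain in 3, and cell cycle, p53 targets and the interferon list, which has enough measured genes only on the scanner files, in 1 each. Apart from the turned signs and the fewer units, the cause was not tested. Of 76 named genes, 12 differed in sign with replicate 2 turned (QPCT, BAX, HBA1, ACADM, IGF1, HSPA2, CRYAB, RBP4, DKK1, SLC9A3, DSG2 and SCGB1A1), 16 with replicate 1 turned and at most 3 under any other setting. The share of spots well above background, 54.4% in green on replicate 1, limits what the arrays cover.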

Other observations

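The gene calls with 1 probe per gene on replicates 2 and 3 alone were chosen only after the result was seen, while the list tests without replicate 1 were planned. On these arrays, whose dyes are opposite, limma called 156 genes with 1 probe per gene, 49 higher and 107 lower in frozen embryos. Each call rests on 2 arrays and on the direction of replicate 2, which is not stated; with its sign turned r of these arrays is -0.48, and what they share would follow the dye. The genes named here were chosen after their values were seen. Haemoglobin HBB2 had a mean of -3.68 over replicates 2 and 3 (limma, adjusted p = 0.00014), and ALAS2, the enzyme that starts haem synthesis in red cells, had -1.47 (0.010). CPS1, an enzyme of the urea cycle, had -2.19 (0.0013), FGB, a fibrinogen chain, had -1.68 (0.0023) and PTGS2, a prostaglandin synthase, had -1.88 (0.0068). ANXA3 had -1.75 (0.0023) and SERPINH1, a chaperone of collagen, had -1.30 (0.010). On replicate 1 each of these 7 genes was above 0, with HBB2 at 2.62, CPS1 at 0.97, SERPINH1 at 0.67 and FGB at 0.56.

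Higher in frozen embryos on replicates 2 and 3 were HADHA (0.78, limma adjusted p = 0.031) and HADHB (0.81, 0.029), which form the mitochondrial trifunctional protein of fatty acid oxidation. CLDN3, a tight junction protein, had 0.87 (0.031) and GPRC5A had 1.25 (0.011). On replicate 1 they were at -0.93, -0.75, -0.65 and -0.78. The respiratory chain list passed as higher on replicates 2 and 3 (camera, adjusted p = 0.019), beside the hypoblast (1.3e-09), matrix (0.00036) and unfolded protein response (0.0015) lists as lower. With an estimated correlation 0 of these 4 passed, each at an adjusted p = 0.81. The estimates were 0.63 for the respiratory chain, -0.055 for the hypoblast, -0.029 for the matrix and -0.067 for the unfolded protein response. On replicates 2 and 3 alone each estimate reflects only how unevenly the genes split between higher on replicate 2 and higher on replicate 3. It does not show whether the genes vary together. With so few arrays that test has little power, so the lost calls do not measure the correlation of the genes. PHGDH, PSAT1 and FN1 were below 0 on all 3 arrays and passed on replicates 2 and 3 (limma, adjusted p = 0.0013, 0.0014 and 0.031).

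As replicate 2 is read, several lists lay on opposite sides of 0 on replicates 1 and 2; with its sign turned r of these arrays is 0.36 and the medians would lie on the same side. Junction genes were below 0 for 14 of 19 members on replicate 1 and 4 on replicate 2, heat shock genes for 12 and 3 of 14, DNA methylation and histone genes for 16 and 3 of 20, and autophagy genes for 16 and 6 of 20. Their medians on replicate 1 were -0.25, -0.22, -0.31 and -0.44, and on replicate 2 they were 0.28, 0.22, 0.19 and 0.18.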
